A study of Homo sapiens with 15 samples.

How the data were processed

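Gene expression was measured in MV4-11 cells, an established human acute myeloid leukemia line, after 24 h with DMSO or a compound. Total RNA was made into biotin-labelled sense cDNA and hybridised to an Affymetrix whole-transcript human array, per the labels' protocols. The 5 groups were DMSO, DW71177 at 300 nM, DW71374 at 300 nM, OTX015 at 300 nM and RVX208 at 5 uM, with 3 arrays each and 15 in all. Groups and replicate numbers were taken from the sample titles. The labels describe wells treated in triplicate and do not say whether these came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

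The deposited table held log2 signals for 44629 features, and its scale was inferred from the values. Near-identical quartiles in all arrays showed that the authors had normalized between arrays before deposit. Their background correction, normalization method, software and genome build are not given in the sources used here. A normalization of this kind removes a change shared by all genes, so every difference reported is relative to the array as a whole. For 29 to 62 genes per group the 3 replicate arrays held the same deposited value, for a reason not given in the sources used here, and these genes were kept. Arrays give no counting depth, and the number of arrays limits the precision.

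Features were named through the platform annotation. Of the 44629 features, 15835 named exactly 1 gene, 0 named several and 28794 were unnamed in that table. The symbols of 15835 features matched a RefSeq gene table of the human genome, which was used for names and gene types only, and no coordinates are given because the array's build is unnamed. Where several features named a gene, as for 651 genes, the feature with the highest mean over the 15 arrays was used. This left 14812 genes, of which 11910 were protein-coding, 1387 long noncoding RNAs, 1022 microRNAs, 443 transcribed pseudogenes and 50 of other types. No level filter was applied, and no background level was given, so folds of genes with a group mean under 5, a level chosen after the values were seen, are at best lower bounds. Histone genes, HOXA9, CDKN1A and SERPINI1 were not among the genes analysed here.

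Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings) on the log2 values, in a single fit of the 5 group means with 10 residual degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 14812 genes, and a gene was called changed at an adjusted p under 0.05. All 10 comparisons between groups were made. Values are log2 differences of group means ± the standard error of the fit, with 95% confidence intervals where given, and SD refers to the 3 arrays of a group.

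Before the data were examined, 25 gene lists were fixed. They covered genes lowered and raised by BET inhibitors, BET proteins with the kinase complex P-TEFb, ribosome biogenesis with other MYC targets, cytosolic ribosomal proteins, DNA replication, mitosis, the HOXA-MEIS1 program of KMT2A-fusion leukemia and replication-dependent histones. Others covered monocyte and macrophage differentiation, neutrophil granule proteins, pro-survival and pro-apoptotic BCL2 family members, p53 targets, inflammatory cytokines, interferon-stimulated genes, cholesterol synthesis and uptake, and apolipoproteins with complement and coagulation factors. The remaining lists covered aryl hydrocarbon receptor targets, amino acid and unfolded protein stress, autophagy and lysosome, glycolysis, and markers of lymphoid, erythroid and megakaryocytic, and epithelial and stromal cells. Lists with at least 3 measured members were tested, a minimum set after the annotation had been seen, which left 22 lists and excluded 3. Each list was tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 22 lists of a comparison. Camera with an estimated correlation and fry, which asks only whether a list's genes move one way, were alternatives. For called lists with both p-values given, the estimated correlation gave the larger one, including where the call held. Very small camera p-values at the preset correlation are therefore not read as the strength of the evidence. Member counts are given over all genes tested and, where they differ, adjusted over the list alone.

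The genes named were chosen by a rule fixed before the data were examined. It took the 6 largest rises and 6 largest falls per compound against DMSO among called genes whose 3 arrays all lay on one side of the 3 control arrays, and 4 of each per pair of compounds. Genes with provisional symbols, noncoding RNAs, pseudogenes and sex-linked markers were passed over. It also took 20 genes fixed in advance, of which 12 were measured, and up to 4 members of each list with the smallest p in the comparison.

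The size of each response relative to OTX015 was the slope across genes of a compound's log2 changes on those of OTX015, after the noise variance and the noise covariance from the shared DMSO arrays had been taken out. Correlations of responses were set beside 100 simulations of unchanged groups sharing the DMSO arrays. The alternatives tried were quantile normalization, median centring, only genes above the median of mean levels, the mean of features, all features, another variance model, a fit of only the 6 arrays compared, array weights, the replicate number as a block, and each array left out in turn. Leaving out the 2 most deviant arrays and testing lists of any size were added after seeing the data. The steps were tested on simulated data with known changes. Simulated DW71374 arrays took the DMSO group means, known changes and independent normal noise with limma's variances. Against simulated DMSO arrays, 69% of genes changed by a log2 of 0.5 and 98% of those changed by 1 were recovered. Among 14812 genes 8 unchanged genes were called. No correlation between genes was simulated, so these shares may be too favourable for the real arrays.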

Results

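The experiment set 4 compounds, described in the labels as BET inhibitors, against the vehicle DMSO in MV4-11 cells. BET proteins are a family of acetyl-lysine readers. This line carries a KMT2A-AFF1 fusion and an activating FLT3 duplication. OTX015 (birabresib) binds both bromodomains of the BET family, and RVX208 (apabetalone) prefers the second bromodomain. DW71177 and DW71374 are test compounds known here by code name, and both were used at the 300 nM of OTX015, whereas RVX208 was used at 5 uM. Each of the 5 groups held 3 arrays taken at 24 h. Array medians lay between 3.72 and 3.79 on the log2 scale, and replicate arrays correlated at 0.992 to 0.995 across genes. The first principal component held 43.1% of the variance. On it the DMSO arrays scored -17.0 to -16.2, the DW71374 arrays -16.8 to -16.2, the RVX208 arrays -1.04 to -0.581, the DW71177 arrays 12.9 to 13.8 and the OTX015 arrays 19.6 to 21.6.

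The comparison of OTX015 with DMSO asked what a pan-BET inhibitor changed in these cells. MYC was 2.68-fold lower with OTX015 (log2 -1.42 ± 0.054, n = 3 and 3, limma adjusted p = 7.7e-10), and HEXIM1, which encodes an inhibitor of P-TEFb, was 3.14-fold higher (1.65 ± 0.068, limma adjusted p = 1.7e-09). Among the largest falls, the macrophage pore protein gene MPEG1 fell 20.1-fold (log2 -4.33 ± 0.10), the chemokine receptor CCR2 fell 15.4-fold, and GPR183, OCSTAMP, IGF1 and ENPP2 fell between 6.94- and 8.37-fold. No background level was given, so in this and every later comparison the fold of a gene whose lower group mean lay under 5, not far above the array medians, is at best a lower bound. With OTX015 this held for MPEG1, CCR2 and OCSTAMP at 4.35, 4.32 and 3.98, and in DMSO for SAT1 and ARRDC3. ARRDC4 rose 6.76-fold (log2 2.76 ± 0.068), followed by the polyamine acetyltransferase SAT1 at 4.03-fold and by IER3, ARRDC3, ZYG11B and SLFN5 at 3.27- to 3.92-fold. With the mean of its features the IER3 difference was smaller, 1.30 against 1.97 on the log2 scale. A second, dimmer HEXIM1 feature also rose less, by 0.854 with OTX015, 0.725 with DW71177 and 0.506 with RVX208. BCL2 fell 2.28-fold and CDK6 1.76-fold, while MCL1 rose 1.55-fold, the pro-apoptotic BCL2L11 1.48-fold, MEIS1 1.49-fold and BRD2 1.43-fold. FLT3 differed by 0.07 ± 0.058, MYB by 0.07 ± 0.064, CD14 by 0.01 ± 0.12 and APOA1 by 0.06 ± 0.19, and none of these passed the test. In all, limma called 3800 of 14812 genes (25.7%), 1656 higher and 2144 lower, of which 59 rose and 138 fell at least 2-fold.

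Genes of cell growth and division fell together with OTX015. Of 26 measured DNA replication genes 25 fell, with a list median of -0.81 (camera adjusted p = 6.2e-23). CDC6, which loads the replicative helicase, fell 2.36-fold, and the helicase genes MCM2, MCM5 and MCM6 fell 2.17-, 1.90- and 1.82-fold. Of 23 ribosome biogenesis and other MYC target genes 22 fell (median -0.77, camera adjusted p = 2e-21), among them MYBBP1A by 2.10-fold and NIP7 by 2.12-fold. Of 28 mitosis genes 26 fell (median -0.52, camera adjusted p = 8.2e-18), including BUB1B, TOP2A, MAD2L1 and CCNA2. Of 10 genes known to be lowered by BET inhibitors 9 fell (median -1.20, camera adjusted p = 2.1e-13). Of 22 cytosolic ribosomal protein genes 10 fell, 11 adjusted over the list alone, with a median of -0.15 and a camera adjusted p of 0.0013, which an estimated correlation raised to an adjusted p = 0.05, no longer under the threshold.

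Cholesterol synthesis and uptake genes fell with OTX015 in 13 of 16 cases (median -0.56, camera adjusted p = 7.1e-11), led by TMEM97 at 2.87-fold, the sterol demethylation enzyme gene MSMO1 at 2.71-fold and HMGCS1 at 2.06-fold. Autophagy and lysosome genes rose in 12 of 19 cases, 14 adjusted over the list alone (median 0.37, camera adjusted p = 5.1e-09). The lysosomal genes PSAP and CTSB rose 2.27- and 1.81-fold and the autophagy gene GABARAPL2 rose 1.77-fold. Of 21 interferon-stimulated genes 4 rose, 3 adjusted over the list alone: IRF7, IRF9, RSAD2 and HERC5 (list median 0.15, camera adjusted p = 0.034). This list's call was lost with an estimated correlation, at an adjusted p = 0.057. Quantile normalization, restriction to brighter genes and omission of the 2 most deviant arrays each ended it too, as did omission of OTX015 replicate 3.

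The other lists passed no camera test with OTX015, although some members changed both ways. Of 20 monocyte and macrophage genes 2 rose and 5 fell (median 0.01, mean -0.11, camera adjusted p = 0.5). CD86 rose 2.51-fold whereas CSF1R, LYZ and IRF8 fell 2.93-, 2.03- and 1.70-fold. Of 10 neutrophil granule genes 5 fell, including CTSG by 2.04-fold (camera adjusted p = 0.077). Of 16 genes of the HOXA-MEIS1 program 4 rose and 5 fell, with KIT 2.41-fold lower and LMO2 1.40-fold higher (camera adjusted p = 0.48). Of 17 inflammatory cytokine genes 4 rose and 3 fell, or 5 and 3 adjusted over the list alone, and TNF, CCL5 and ICAM1 rose 2.06-, 2.23- and 1.86-fold (camera adjusted p = 0.19). Of 13 p53 targets 6 rose and 2 fell, with TP53INP1 at 2.38-fold higher (camera adjusted p = 0.16). Of 15 amino acid and unfolded protein stress genes 3 rose and 6 fell, including PSAT1 and PHGDH of serine synthesis, 1.96- and 1.93-fold lower (camera adjusted p = 0.48).

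Smaller lists were mixed as well with OTX015. Of 5 pro-survival BCL2 family genes 1 rose and 2 fell (camera adjusted p = 0.19), and of 10 pro-apoptotic members 1 rose and 3 fell, 4 adjusted over the list alone (camera adjusted p = 0.48). Of 8 BET protein and P-TEFb genes 2 rose and 1 fell (camera adjusted p = 0.14), the fall being MEPCE at 1.17-fold. Of 8 glycolysis genes HK1 rose and GPI, HK2 and LDHA fell (camera adjusted p = 0.19). Of 18 apolipoprotein, complement and coagulation genes 2 rose and 2 fell, with THBD 3.43-fold lower and CFD 1.81-fold higher, and the median of 0.04 and the upward test differed in sign from the mean of -0.08 (camera adjusted p = 0.86). Among markers of other cell types, 2 of 9 lymphoid genes fell, NKG7 by 2.29-fold and PRF1 by 1.27-fold (camera adjusted p = 0.33). PF4 was the single one of 7 erythroid and megakaryocyte genes that fell, 0 adjusted over the list alone (list median 0.06, mean -0.07, camera adjusted p = 0.97), and 0 of 8 epithelial and stromal genes changed in limma. Of the 3 lists with fewer than 3 measured members, HEXIM1 stood for the genes raised by BET inhibitors and 0 histone genes were measured. TIPARP and NFE2L2 stood for aryl hydrocarbon receptor targets, and TIPARP rose by 0.76 ± 0.086 (limma adjusted p = 1.4e-05).

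**Figure D1:**
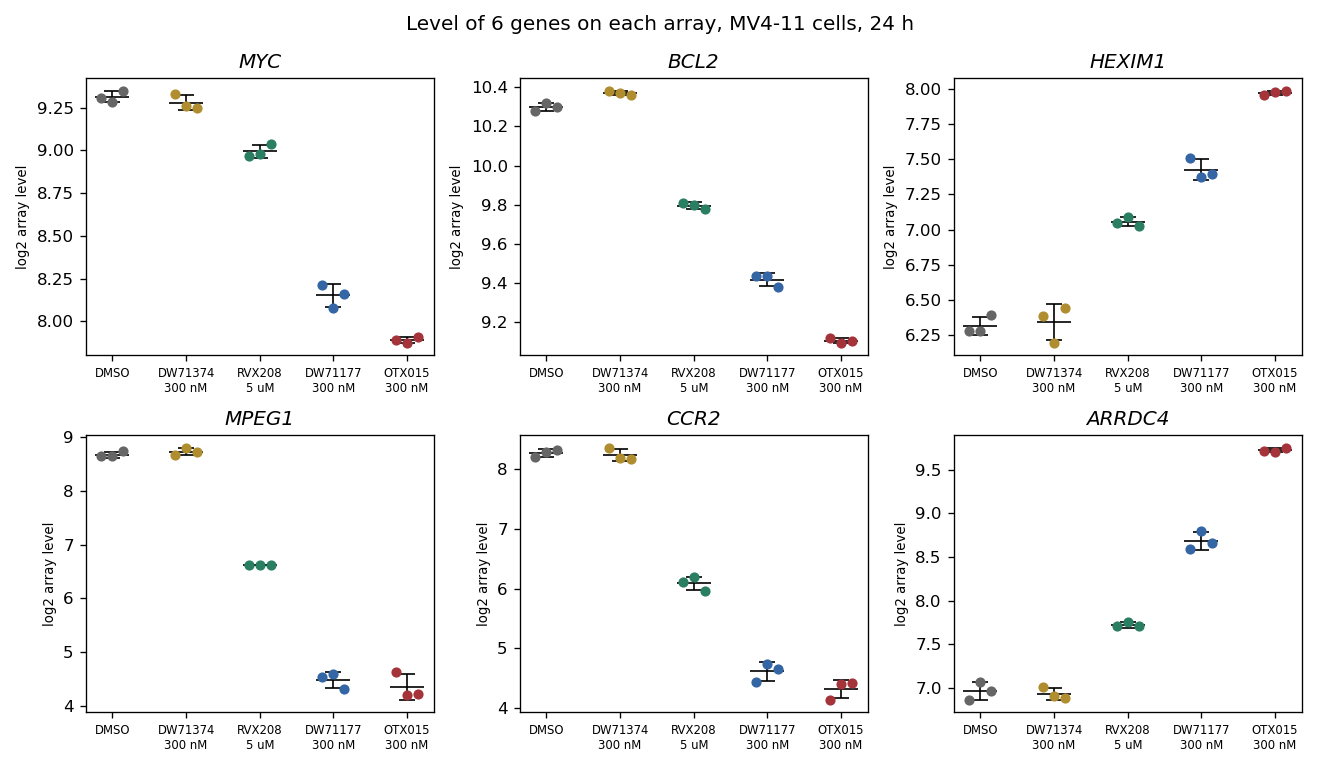
Log2 array levels of 6 genes in MV4-11 cells after 24 h; each point is 1 array, the horizontal bar is the mean of the 3 arrays and the whiskers are 1 SD. MYC, BCL2, MPEG1 and CCR2 were lower and HEXIM1 and ARRDC4 higher with RVX208, DW71177 and OTX015, while DW71374 arrays lay near DMSO.

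DW71177 at 300 nM, compared with DMSO, changed many of the same genes. MYC fell 2.24-fold (log2 -1.16 ± 0.054, n = 3 and 3, limma adjusted p = 9.2e-09) and HEXIM1 rose 2.16-fold (1.11 ± 0.068, limma adjusted p = 1.3e-07). MPEG1 fell 18.4-fold and CCR2 12.5-fold, followed by GPR183, ENPP2, OCSTAMP and the IgM receptor gene FCMR at 4.67- to 7.75-fold, those of MPEG1, CCR2, OCSTAMP and FCMR being such lower bounds. ARRDC4 rose 3.29-fold, and ZYG11B, ARRDC3, the thioredoxin-binding arrestin gene TXNIP, IER3 and KIAA0513 rose 2.49- to 2.87-fold. BCL2 fell 1.84-fold and CDK6 1.54-fold, and MCL1, BCL2L11, MEIS1 and BRD2 rose 1.35-, 1.32-, 1.39- and 1.21-fold. FLT3 differed by 0.02 ± 0.058 and MYB by 0.08 ± 0.064, neither passing the test, and nor did CD14 at -0.18 ± 0.12 or APOA1 at 0.12 ± 0.19. Limma called 2937 genes (19.8%), 1474 higher and 1463 lower, and 27 of them rose and 62 fell at least 2-fold. Of these calls 1230 were shared with OTX015 upward, where independent lists would share 165, and 1334 downward against 212. The number called in opposite directions was 0. In 20 draws of unchanged groups sharing the DMSO arrays 0 calls were shared. Groups without changes leave few calls to share, so these draws cannot show how far the shared controls raise the overlap.

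Growth lists fell with DW71177 too. Ribosome biogenesis and MYC target genes fell in 21 of 23 cases (median -0.59, camera adjusted p = 2.5e-22), with MYBBP1A at 1.94-fold. DNA replication genes fell in 21 of 26, 22 adjusted over the list alone (median -0.51, camera adjusted p = 6e-17), with CDC6 at 1.82-fold and MCM2 at 1.62-fold. Mitosis genes fell in 23 of 28, 24 adjusted over the list alone (median -0.36, camera adjusted p = 1.9e-14), and genes known to be lowered by BET inhibitors in 9 of 10 (median -0.87, camera adjusted p = 4.7e-14). Cholesterol genes fell in 14 of 16, 15 adjusted over the list alone (median -0.54, camera adjusted p = 8.2e-14), led by MSMO1 at 2.39-fold. Autophagy and lysosome genes rose in 10 of 19, 11 adjusted over the list alone (median 0.29, camera adjusted p = 9.7e-09), with PSAP at 2.21-fold. Of 10 neutrophil granule genes 5 fell, and adjusted over the list alone 6 fell and 1 rose, with CTSG 2.11-fold and BPI 1.59-fold lower (camera adjusted p = 0.0052). RPS3 was the single one of 22 cytosolic ribosomal protein genes that fell, and 0 did adjusted over the list alone (camera adjusted p = 0.016). With an estimated correlation the calls of these last 2 lists were lost, each at an adjusted p = 0.12, and both were also lost among the brighter genes alone.

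The 14 other lists passed no camera test with DW71177. Of 20 monocyte and macrophage genes 4 rose and 5 fell (camera adjusted p = 0.19), with CD86 2.18-fold higher and LYZ and the scavenger receptor gene CD36 2.21- and 2.09-fold lower. Of 21 interferon-stimulated genes 5 rose, including IRF7 at 1.70-fold (camera adjusted p = 0.052). Of 13 p53 targets 5 rose and 1 fell, 6 and 2 adjusted over the list alone, and the median of -0.02 differed in sign from the mean of 0.12 (camera adjusted p = 0.3). Of 17 inflammatory cytokine genes 3 rose and 1 fell, 3 and 2 adjusted over the list alone, with CCL5 1.78-fold higher and the neutrophil chemokine gene CXCL8 2.97-fold lower (camera adjusted p = 0.52).

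DW71374 at 300 nM was set against DMSO at the same dose as DW71177 and OTX015. MYC differed from DMSO by -0.04 ± 0.054 (95% confidence interval -0.15 to 0.08, n = 3 and 3, limma adjusted p = 0.99) and HEXIM1 by 0.02 ± 0.068 (-0.12 to 0.17, limma adjusted p = 0.99). BCL2 differed by 0.07 ± 0.047, CDK6 by 0.00 ± 0.063, BRD2 by -0.11 ± 0.058 and MEIS1 by 0.11 ± 0.083. FLT3 differed by -0.07 ± 0.058, MYB by 0.04 ± 0.064, MCL1 by -0.09 ± 0.073 and BCL2L11 by 0.09 ± 0.089. Limma called 0 of 14812 genes, with a smallest adjusted p of 0.6, and 686 genes had an unadjusted p under 0.05 where chance gives 741. The variance models, array weights and other settings tried in limma, and each array left out, also called 0. For 14774 genes (99.7%) the 95% interval of the difference lay within 2-fold either way, and for 14025 (94.7%) within 1.5-fold. Genes of every level are counted here, and for a dim gene a narrow interval does not bound the true fold. All 22 lists held 0 changed members, and camera and fry called 0 lists, with a smallest camera adjusted p of 0.89.

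RVX208 at 5 uM gave smaller changes from DMSO in many of the genes moved by OTX015. CCR2 fell 4.52-fold (log2 -2.18 ± 0.097, n = 3 and 3, limma adjusted p = 3.8e-08) and MPEG1 4.18-fold (-2.06 ± 0.10, limma adjusted p = 1.1e-07). The 3 RVX208 arrays held the same deposited MPEG1 value, as was the case for 59 genes in this group, so its error rests on the other groups and on limma's shrunken variance. FCMR, ENPP2, the interleukin-7 receptor gene IL7R and the lectin gene CD209 fell 3.01-, 2.68-, 2.56- and 2.20-fold, with IL7R and CD209 as low as 3.13 and 4.56 and their folds lower bounds at best. ARRDC3 rose 2.01-fold, and HIC1, POPDC1, ZYG11B, ROPN1L and SLFN5 rose 1.75- to 1.85-fold. Of these, ARRDC3, ZYG11B and SLFN5 rose more with OTX015. HIC1 did not, at a log2 of 0.89 with RVX208 and 0.192 with OTX015, and POPDC1 rose by a similar 0.867 and 0.913. HEXIM1 rose 1.67-fold, MYC fell 1.25-fold (log2 -0.32 ± 0.054, limma adjusted p = 0.0027), BCL2 fell 1.42-fold, CDK6 fell 1.26-fold and MCL1 rose 1.22-fold. BRD2 at 0.20 ± 0.058, MEIS1 at 0.17 ± 0.083 and BCL2L11 at 0.22 ± 0.089 did not pass the test (limma adjusted p = 0.063, 0.29 and 0.18). Nor did FLT3 at 0.02 ± 0.058, MYB at -0.02 ± 0.064, CD14 at -0.04 ± 0.12 or APOA1 at -0.125 ± 0.19 (limma adjusted p = 0.91, 0.9, 0.91 and 0.8). CD14 and APOA1 were dim, under 5 in both groups. Limma called 966 genes (6.52%), 505 higher and 461 lower, of which 1 rose and 12 fell at least 2-fold. The count ranged from 564 to 636 when any single DMSO or RVX208 array was left out, and was 609 from the 6 arrays alone, 1558 among brighter genes and 1485 with another variance model.

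Ribosome biogenesis and MYC target genes fell with RVX208 in 14 of 23 cases, 20 adjusted over the list alone (median -0.25, camera adjusted p = 1.6e-15). Genes known to be lowered by BET inhibitors fell in 7 of 10 (median -0.41, camera adjusted p = 1e-11). Mitosis genes fell in 8 of 28 and DNA replication genes in 9 of 26, or 13 and 14 adjusted over each list alone, both with a median of -0.18 (camera adjusted p = 1.9e-09 and 1.2e-08). MCM6 fell 1.25-fold and BUB1B 1.33-fold. Cholesterol genes fell in 4 of 16, 9 adjusted over the list alone (median -0.23, camera adjusted p = 1.7e-07), and autophagy and lysosome genes rose in 6 of 19, 8 adjusted over the list alone (median 0.19, camera adjusted p = 2.4e-08). Of 10 neutrophil granule genes CTSG, PRTN3, BPI and MPO fell 1.27- to 1.76-fold (median -0.32, camera adjusted p = 8e-05). Of 15 amino acid and unfolded protein stress genes 5 fell and 1 rose (median -0.12, camera adjusted p = 0.016), with VLDLR and PHGDH both 1.62-fold lower. Of 8 BET protein and P-TEFb genes HEXIM1 alone rose, 2 adjusted over the list alone (median 0.07, camera adjusted p = 0.031), and this call was lost with an estimated correlation at an adjusted p = 0.11. The list also lost its call among brighter genes and in the fit of 6 arrays.

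**Figure D2:**
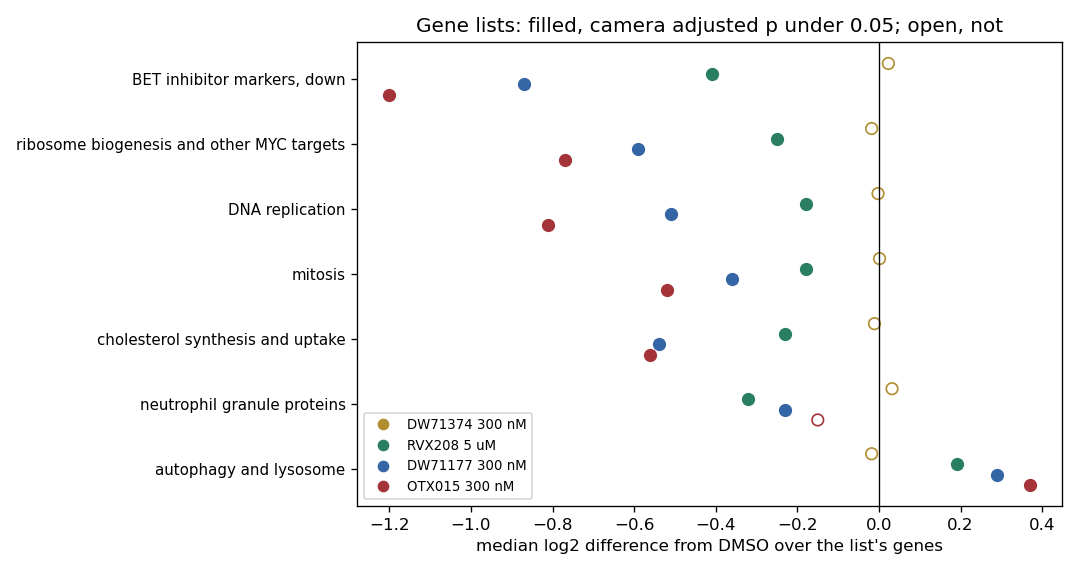
Median log2 difference from DMSO over the measured genes of 7 lists (horizontal axis) for each compound, 3 arrays per group; filled points passed camera at an adjusted p under 0.05 and open points did not. The DNA replication median was -0.81 with OTX015, -0.51 with DW71177 and -0.18 with RVX208.

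DW71177 and OTX015 were compared directly at their shared dose of 300 nM. ARRDC4 was 2.06-fold lower with DW71177 than with OTX015 (log2 -1.04 ± 0.068, interval -1.19 to -0.89, n = 3 and 3, limma adjusted p = 1.1e-05), and SAT1, TNF and GPR84 were 1.60- to 1.90-fold lower. The adapter gene SCIMP was 1.60-fold higher with DW71177 (0.68 ± 0.056, limma adjusted p = 6.1e-05), as were MT1M, KRTAP21-1 and MAP2K6 by 1.67- to 1.71-fold. A second, dimmer KRTAP21-1 feature differed the other way (-0.44 with DW71177 and 0.05 with OTX015 against DMSO), and with the mean of its features the call was lost at 0.13. MT1M, KRTAP21-1, MAP2K6 and GPR84 were dim, at 3.57 to 3.96 in the lower group, so their folds are lower bounds at best. MYC was 1.20-fold higher (0.26, interval 0.14 to 0.38, limma adjusted p = 0.037), BCL2 1.24-fold higher and HEXIM1 1.46-fold lower (-0.54, interval -0.69 to -0.40, limma adjusted p = 0.0035, and -0.34 with the mean of its features). BRD2 at -0.25 (interval -0.37 to -0.12) and CDK6 at 0.20 (0.06 to 0.33) did not pass the test. Limma called 186 genes, 159 higher and 27 lower, with ARRDC4 alone beyond 2-fold. For 14764 genes (99.7%) the interval of the difference lay within 2-fold, and for 13838 (93.4%) within 1.5-fold. Dim genes are counted here too, and their intervals do not bound the true fold.

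The number of genes that differed between DW71177 and OTX015 depended on the fit. It was 1 from the 6 arrays alone, 564 among brighter genes and 497 with another variance model, 112 after median centring and 118 with array weights. Left out singly, DW71177 replicates 1, 2 and 3 gave 106, 71 and 74 and OTX015 replicates 1 and 3 gave 80 and 104, and omission of the 2 most deviant arrays gave 31. As the fit of 6 arrays called 1 gene, at most 1 of the genes named for this pair kept its call there. The MYC, HEXIM1, BCL2 and TNF calls were among those lost, and that of MYC was also lost after median centring and quantile normalization. DNA replication genes were higher with DW71177 than with OTX015 in 13 of 26 cases, 25 adjusted over the list alone (median 0.28, camera adjusted p = 3.1e-26). MCM5, MCM6, TYMS and MCM2 were 1.25- to 1.34-fold higher. Mitosis genes were higher in 2 of 28, 15 adjusted over the list alone (median 0.18, camera adjusted p = 4.5e-12), the 2 being MAD2L1 and KIF2C. Ribosome biogenesis genes were higher in 0 of 23 in limma, 9 adjusted over the list alone (median 0.16, camera adjusted p = 1.3e-08). Genes known to be lowered by BET inhibitors were higher in 4 of 10, 7 adjusted over the list alone (camera adjusted p = 6.9e-10), with CD180 at 1.56-fold. BET protein and P-TEFb genes and autophagy genes were called lower by camera (adjusted p = 0.013 and 0.02), and both calls were lost with an estimated correlation, at an adjusted p = 0.095 and an adjusted p = 0.085. The other 4 of the 6 called lists held, but an estimated correlation can raise the p-value of a held call by far. For DNA replication genes against a scaled OTX015 response, tested below, it raised the camera adjusted p from 7e-11 to 0.0048.

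At the same 300 nM, DW71374 differed from both active compounds. Against OTX015, MYC was 2.62-fold higher with DW71374 (log2 1.39 ± 0.054, n = 3 and 3, limma adjusted p = 9.8e-10) and HEXIM1 3.09-fold lower (interval -1.78 to -1.48). MPEG1, CCR2, GPR183 and IGF1 were 7.43- to 20.9-fold higher, and ARRDC4, ARRDC3, SLFN5 and IER3 3.59- to 6.91-fold lower, with the folds of MPEG1, CCR2 and ARRDC3 lower bounds at best. Limma called 3730 genes between these compounds, 2081 higher and 1649 lower with DW71374, 139 and 58 of them at least 2-fold. Camera called 8 lists, and all 8 held with an estimated correlation. DNA replication genes were higher in 25 of 26 (median 0.78, camera adjusted p = 1.4e-23) and autophagy and lysosome genes lower in 11 of 19, 13 adjusted over the list alone (median -0.35, camera adjusted p = 6.2e-09).

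Between DW71177 and DW71374, MYC was 2.19-fold lower with DW71177 (log2 -1.13 ± 0.054, interval -1.24 to -1.01, n = 3 and 3, limma adjusted p = 1.3e-08) and HEXIM1 2.12-fold higher (interval 0.94 to 1.23). MPEG1, CCR2, GPR183 and ENPP2 were 6.16- to 19.1-fold lower, and ARRDC4, ARRDC3, SLFN5 and the kinase gene TESK2 2.61- to 3.36-fold higher, with the folds of MPEG1, CCR2 and ARRDC3 lower bounds at best. Limma called 2887 genes, 1478 higher and 1409 lower, of which 27 and 63 differed at least 2-fold. Camera called 10 lists and 6 held with an estimated correlation, including ribosome biogenesis (22 of 23 genes lower, median -0.59, camera adjusted p = 1.5e-23). The calls of cytosolic ribosomal proteins, neutrophil granule, interferon-stimulated and amino acid stress genes were lost, at an adjusted p = 0.12, an adjusted p = 0.12, an adjusted p = 0.068 and an adjusted p = 0.079.

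RVX208 was compared with the other compounds at a different dose, 5 uM against 300 nM. Against OTX015, MYC was 2.15-fold higher with RVX208 (log2 1.10 ± 0.054, n = 3 and 3, limma adjusted p = 2.6e-08) and HEXIM1 1.88-fold lower, MPEG1, IGF1, GPR183 and SCIMP were 4.02- to 4.81-fold higher (for MPEG1 a lower bound at best), and ARRDC4 was lower by a log2 of -2.00, with IER3, SAT1 and TNF 2.24- to 2.85-fold lower. Limma called 2153 genes, 1405 higher and 748 lower, and 1353 from the 6 arrays alone. DNA replication genes were higher in 24 of 26, 25 adjusted over the list alone (median 0.55, camera adjusted p = 4.4e-29). Camera called 7 lists, of which cytosolic ribosomal proteins were lost with an estimated correlation, at an adjusted p = 0.068.

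Against DW71177, MYC was 1.79-fold higher with RVX208 (log2 0.84 ± 0.054, n = 3 and 3, limma adjusted p = 1.1e-06) and HEXIM1 1.29-fold lower. MPEG1, GPR183, IGF1 and CCR2 were 2.77- to 4.41-fold higher, and ARRDC4, IER3, EFR3B and GXYLT2 1.70- to 1.95-fold lower, with the folds of MPEG1, CCR2, EFR3B and GXYLT2 lower bounds at best. Limma called 663 genes, 400 higher and 263 lower. This count was 75 from the 6 arrays alone, 1169 among brighter genes and 1100 with another variance model, and 426, 348, 344 and 368 without DW71177 replicate 1 and RVX208 replicates 1, 2 and 3. The 7 lists camera called all held with an estimated correlation, and ribosome biogenesis genes were higher in 17 of 23, 21 adjusted over the list alone (median 0.35, camera adjusted p = 4.8e-24). Of 20 monocyte and macrophage genes 4 were higher and 1 lower (median 0.08, camera adjusted p = 0.014).

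Against DW71374, CCR2 was 4.42-fold and MPEG1 4.33-fold lower with RVX208 (log2 -2.15 ± 0.097 and -2.12 ± 0.10, n = 3 and 3, limma adjusted p = 4.6e-08 and 7.9e-08), as were FCMR and ENPP2 by 3.09- and 2.72-fold. ARRDC3, SLFN5, SPATA31H1 and ROPN1L were 1.83- to 2.06-fold higher. A second, dimmer SPATA31H1 feature differed the other way (-0.13 with RVX208 and 0.09 with DW71374 against DMSO), and with the mean of its features the call was lost at 0.35. MYC was 1.22-fold lower and HEXIM1 1.64-fold higher. Limma called 955 genes, 513 higher and 442 lower, with 576 from the 6 arrays alone, 1482 among brighter genes and 1445 with another variance model. Without DW71374 replicates 1 and 2 and RVX208 replicates 1 and 2 in turn, the count was 610, 606, 599 and 579. Camera called 12 lists and 10 held with an estimated correlation. The HOXA-MEIS1 program (1 gene higher and 4 lower) and p53 targets (3 higher) were lost, at an adjusted p = 0.31 and an adjusted p = 0.071.

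The responses were also compared over all genes. On the scale of the OTX015 response, the slope was 0.787 ± 0.01 for DW71177, 0.411 ± 0.0045 for RVX208 at its higher dose, and -0.00239 ± 0.0092 for DW71374. Each SD is over the compound's 3 arrays, with the OTX015 and DMSO means held fixed. Across genes, which are not independent replicates, the log2 changes of DW71177 and OTX015 correlated at 0.882, those of DW71177 and RVX208 at 0.778 and those of OTX015 and RVX208 at 0.726. Unchanged groups sharing the DMSO arrays gave 0.498 in simulation. The covariances were 0.0743, 0.0383 and 0.0424 for these pairs against a simulated 0.00659. For DW71374 the correlations with DW71177, OTX015 and RVX208 were 0.244, 0.195 and 0.343, and the covariances 0.00776, 0.00736 and 0.00756. The slopes took out a noise covariance from the spread within groups, not the simulated 0.00659. Small excesses over that simulated value are therefore not read as a response. The simulated 0.498 holds where both groups are unchanged. It is no baseline for these DW71374 correlations, because real changes in the partner add variance and lower the correlation. RVX208 shared 460 upward and 429 downward calls with OTX015, where independent lists would share 56 and 67, and 2 genes, LCE2D and PTPRN2-AS1, named after their values were seen, were called in opposite directions. It shared 477 upward and 422 downward calls with DW71177, against 50 and 46, and 0 in opposite directions. With 3 DMSO arrays the control could not be split into separate sets of at least 2, so part of these excesses may come from the shared controls.

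**Figure D3:**
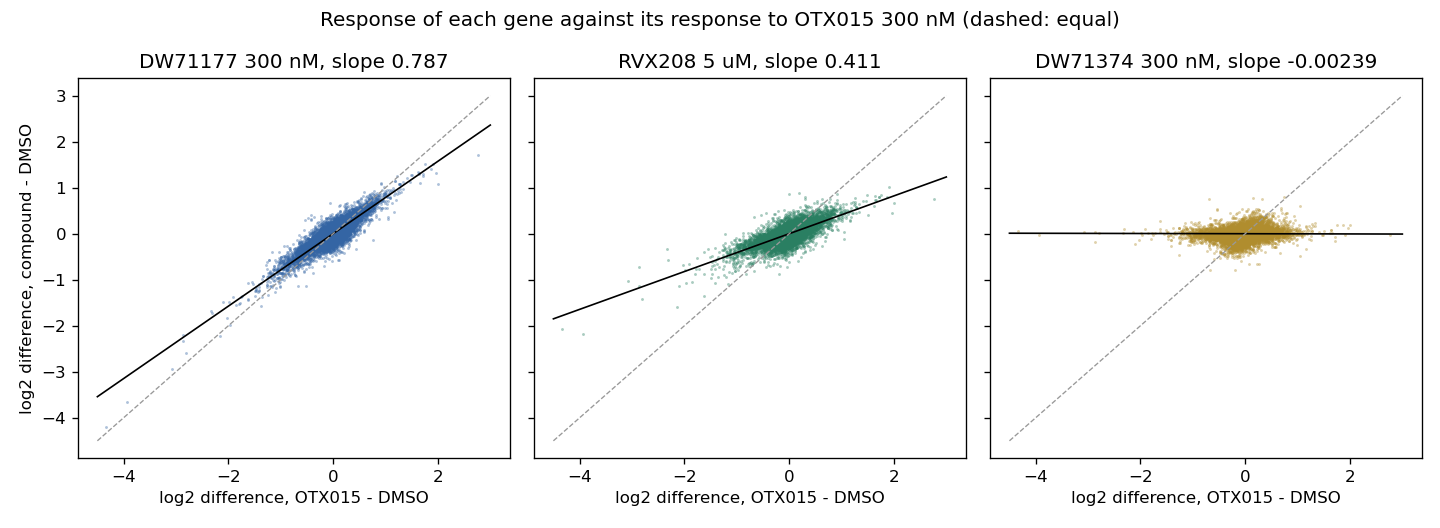
Log2 difference from DMSO of each gene with DW71177, RVX208 or DW71374 (vertical axis) against that with OTX015 (horizontal axis); the solid line is the noise-corrected slope and the dashed line marks equal changes. The slopes were 0.787, 0.411 and -0.00239.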

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

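The tests on scaled responses of gene lists, both tests on DW71374 and all tests on other splits of the arrays were chosen after the results had been seen; the count of genes departing from a scaled RVX208 response and the test leaving out single arrays were not.

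Features with no gene name here carried signal outside the measurements reported above. Of 28794 such features limma called 2058 changed with OTX015 (1006 higher and 1052 lower), 1311 with DW71177 (640 and 671) and 287 with RVX208 (138 and 149). These were 7.15%, 4.55% and 0.997% of the features, below the 25.7%, 19.8% and 6.52% of named genes. With DW71374 limma called 0, with 1393 at an unadjusted p under 0.05.

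DNA replication genes were lower with OTX015 than with DW71177 by a median of 0.28. If DW71177 only gave a uniformly smaller response, the list would match 0.787 times the OTX015 changes, but its median stayed above that by 0.11 ± 0.019, with 25 of 26 genes above (camera adjusted p = 7e-11, and an adjusted p = 0.0048 with an estimated correlation). The SD is over the 3 DW71177 arrays, with the OTX015 and DMSO means and the slope held fixed. Over all genes 12 departed singly at a limma adjusted p under 0.05 (7 above and 5 below), with the slope held fixed. CD180 changed by -0.579 with DW71177 and -1.22 with OTX015, and LYZ by -1.15 and -1.02 (limma adjusted p of the departure = 0.014 and 0.029). The bound of 15 used for RVX208 below was not set for DW71177, and a count under it does not show a uniformly smaller response. None of these 12 was in this list, so its departure rests on the list as a whole. An unadjusted p under 0.05 was found for 1577 genes where chance gives 741. This excess goes against a uniformly smaller response, but genes are not independent and it has no spread here. Mitosis genes lay above the scaled response (0.059, camera adjusted p = 0.0066) and cholesterol, neutrophil granule and amino acid stress genes below (-0.11, -0.11 and -0.049, camera adjusted p = 0.0066, 0.0091 and 0.04), all lost with an estimated correlation (an adjusted p = 0.1, 0.051, 0.16 and 0.12), while ribosome biogenesis genes departed by -0.007. A single deviant array was argued against, since the lowest median with any of the 6 arrays left out was 0.27, and no biological explanation was tested.

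RVX208 at 5 uM resembled an OTX015 response scaled by 0.411, and 43 genes departed from it (26 above and 17 below) at a limma adjusted p under 0.05. This count lay between the 15 and 100 set beforehand as bounds for and against a uniformly smaller response. By those bounds it does not decide. For the 43 genes themselves a uniformly smaller response was argued against, with the slope held fixed. SCIMP changed by -0.337 with RVX208 and -2.34 with OTX015 (limma adjusted p of the departure = 8.9e-05), and HIC1 by 0.89 and 0.192 (limma adjusted p = 0.00054). An unadjusted p under 0.05 was found for 1642 genes where chance gives 741, which goes against a uniformly smaller response, but genes are not independent and this excess has no spread here. For DNA replication genes a uniformly smaller response was argued against, as the list lay 0.13 ± 0.0036 above the scaled response (camera adjusted p = 4.1e-10, and an adjusted p = 0.0064 with an estimated correlation). This SD is over the RVX208 arrays alone and leaves out the spread of the OTX015 and DMSO arrays and of the slope. Camera takes in those arrays but holds the slope fixed. The DW71177 test used the same OTX015 and DMSO arrays, so the departures with DW71177 and RVX208 are not independent. Amino acid stress genes lay below the scaled response (-0.12, camera adjusted p = 0.0022, and an adjusted p = 0.04 with an estimated correlation), as did neutrophil granule genes (-0.23, camera adjusted p = 4.4e-05, lost at an adjusted p = 0.055). Dose and selectivity for a bromodomain may each contribute, and the design does not separate them.

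No gene was called for DW71374. A small response of OTX015's kind, missed in single genes, was argued against for responses of 0.1 of that size or more, since the slope was -0.0024 ± 0.0092, while a smaller or differently directed response stays open. That SD holds the OTX015 and DMSO means fixed, and with single arrays left out the slope ranged from -0.0161 to 0.0017. Untreated cells under this label would also give 0 calls, so arrays of treated but unresponsive and of untreated cells cannot be told apart. No biological explanation for the lack of a response was tested.

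Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. The real split was the single one, 1 of 10, with as many called genes for all comparisons except DW71374 with DMSO, where all 10 splits gave 0; the highest other split called 1 gene for RVX208 against DMSO and against DW71177 and 0 in the rest. For lists, 1 split of 10 reached the real count in 7 comparisons, with real and highest other counts of 8 and 7 (DW71177 and OTX015 against DMSO), 9 and 8 (RVX208 against DMSO), 6 and 5 (DW71177 against OTX015), 10 and 8 (DW71177 against DW71374), 7 and 6 (RVX208 against OTX015) and 12 and 7 (RVX208 against DW71374). The count was 4 of 10 splits for DW71374 against OTX015 (8 and 8), 3 of 10 for RVX208 against DW71177 (7 and 7) and 10 of 10 for DW71374 against DMSO (0 and 0). A split of 2 arrays against 1 keeps part of the real difference, so these list counts are not values without an effect. The same split puts the rest of that difference into the spread within groups, which lowers the gene counts of the other splits. Those low gene counts are therefore not values without an effect either, and no conclusion is drawn from them.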

How the results depend on the processing

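Leaving out the 2 most deviant arrays (DW71177 replicate 2 and OTX015 replicate 3) was chosen after seeing the data. No result reversed, and counts within 1.5 times are not repeated here. The cause of each move was not tested. Among values of single genes, 7029 kept their side of the threshold, 304 lost and 68 gained a call, and among single lists 3751, 54 and 89. Counts of genes changed at least 2-fold moved in 12 of their settings and stayed in 145. Of the moves, 9 came with all features, 2 with 1 array left out and 1 without the 2 most deviant arrays.

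With all features the counts were 5872 for OTX015 and DMSO, 5604 for DW71374 and OTX015 and 79 for DW71177 and OTX015, the last also 112 median centred, 564 among brighter genes, 497 with trend and robust variances, 118 with array weights, 1 with 2 groups only and 31 without the 2 deviant arrays. Brighter genes, trend and robust, and 2 groups only gave 1558, 1485 and 609 for RVX208 and DMSO, 1169, 1100 and 75 for RVX208 and DW71177, and 1482, 1445 and 576 for RVX208 and DW71374. With 2 groups only, RVX208 and OTX015 gave 1353. Fry called 18, 19 and 15 lists for DW71177, OTX015 and RVX208 against DMSO, 10 and 19 for DW71177 and DW71374 against OTX015, 18 for DW71177 against DW71374 (6 with an estimated correlation), and 14 and 12 for RVX208 against OTX015 and DW71177.

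Replicate numbers did not pair the arrays: the 30 pairs with the same number correlated at -0.087 to 0.098 in their deviations, and 7 of 15 arrays correlated best with their own number. With the replicate number as a block the count for DW71177 and OTX015 was 107, and the others stayed within 1.5 times (2849, 3719 and 875 for DW71177, OTX015 and RVX208 against DMSO).

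With each array left out in turn the counts ranged from 71 to 139 for DW71177 and OTX015, 564 to 636 for RVX208 and DMSO, 344 to 458 for RVX208 and DW71177, and 579 to 682 for RVX208 and DW71374. The slopes ranged from 0.768 to 0.791 (DW71177), -0.0161 to 0.0017 (DW71374) and 0.397 to 0.418 (RVX208), and with all features were 0.0103 and 0.403 for the last 2. Correlations ranged from 0.212 to 0.312 (DW71177 with DW71374), 0.848 to 0.888 (with OTX015), 0.735 to 0.791 (with RVX208), 0.169 to 0.267 and 0.305 to 0.435 (DW71374 with OTX015 and RVX208) and 0.687 to 0.742 (OTX015 with RVX208). In that order they were 0.167, 0.943, 0.884, 0.133, 0.238 and 0.835 among brighter genes and 0.325, 0.821, 0.693, 0.277, 0.402 and 0.643 with all features. Without the 2 deviant arrays those of DW71177 with DW71374, OTX015 and RVX208 were 0.22, 0.854 and 0.746, and that of OTX015 with RVX208 was 0.709.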

Other observations

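The lists described here were chosen after seeing the data, and some for genes already named above, so no test of a list as a whole is given; rises and falls are limma calls of single genes. Fatty acid synthesis and desaturation genes fell with OTX015 in 10 of 16 cases and rose in 3 (median -0.28). The desaturase gene SCD changed by -2.03 on the log2 scale, ACSL5 by -1.98, FASN by -1.47 and FADS1 by -1.07, each with a standard error of 0.12 or less, while ACSL1 rose by 0.57. With DW71177 8 fell and 1 rose, with SCD at -1.84 and FASN at -1.23, and with RVX208 5 fell, with SCD at -0.68. Cytosolic tRNA synthetase genes fell in 13 of 17 cases with OTX015, 11 with DW71177 and 8 with RVX208, IARS1 showing -0.92, -0.76 and -0.41. With DW71374 limma called 0 members of these lists.

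Among 6 alpha-arrestin genes, TXNIP, ARRDC3, ARRDC4 and ARRDC5 rose with OTX015 and with DW71177, and TXNIP, ARRDC3 and ARRDC4 with RVX208. TXNIP rose by 1.62, 1.34 and 0.59 in that order, whereas ARRDC1 and ARRDC2 passed the test with none of the 3. Mitochondrial ribosomal protein genes fell in 32 of 37 cases with OTX015, 19 with DW71177 and 2 with RVX208. MRPL3, MRPL24 and MRPL27 were higher with DW71177 than with OTX015, by 0.38, 0.56 and 0.33 (list median 0.14).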
